A study of Homo sapiens with 18 samples.

How the data were processed

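RNA from 3 human melanoma cell lines was measured on 18 Affymetrix HG-U133 Plus 2.0 arrays, 1-colour arrays on which each gene is read by 1 or more probe sets. Per the labels' protocols, the cells were grown in serum-supplemented medium and treated with DMSO or A-485, total RNA was extracted with Qiazol and RNeasy columns, and biotin-labelled cRNA was made with an Affymetrix 3' IVT kit before hybridisation. The deposited table holds 1 intensity per probe set and array on a linear scale, and the software, background correction and scaling behind these values are not given in the sources used here. Between 19.3% and 22.9% of the deposited intensities of an array were below 0, the array medians ran from 19.5 to 29.0, and the 75th percentiles from 132 to 209. The deposited values of different arrays were therefore on different scales, and values below 0 have no logarithm.

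Samples were grouped by line, treatment and time from their titles, which gave 12 groups: 6 of DMSO with 2 arrays and 6 of A-485 with 1 array. All columns of the table belonged to these samples. Of 54613 probe sets, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none listed. The symbols were updated to current ones by Entrez identifier, which 41037 probe sets with 1 symbol allowed. Each of the 19775 genes was represented by its probe set with the highest mean over all arrays, and only probe sets with 1 symbol were named.

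Intensities were quantile normalized between arrays on the linear scale, values below a floor of 32 were set to 32, and log2 was taken. The 5645 genes with a mean log2 intensity below 5.007 (a 40th percentile, but not of the 19775 genes, the floor being 5) were dropped, leaving 14130. The plan made before the data were examined was to take the values as deposited with a floor of 1, with quantile normalization of log2 values and a floor of 32 among its alternatives. That setting did not suit intensities that differ in scale between arrays and lie below 0 for about 1 in 5 probe sets, and it was replaced before any test was run, but after the spread of replicates and the intensities of 7 genes (MITF, TYR, PMEL, MLANA, EP300, SOX10 and ACTB) had been looked at. Normalization was moved before the logarithm and the floor because values below 0 have no log2. The calls of the planned setting are printed beside the main ones. Quantile normalization gives every array the same distribution, so a shift shared by most genes cannot be seen after it. The floor compresses differences of dim genes, and a difference printed as "at least" has 1 side at the floor. Sizes with a side within 2-fold of the floor are not exact, and the genes concerned are named.

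A group-means model was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3. The contrasts were A-485 minus DMSO in each line at 6 h and 24 h, the mean of these over the 3 lines at each time, A375 minus the mean of the other lines for that response at each time, 24 h minus 6 h of the mean response, and the DMSO level of A375 minus the mean of the other lines. The residual spread had 6 degrees of freedom, all from the DMSO pairs, with 1.22 more from empirical Bayes moderation. The lone A-485 arrays were assumed to vary like the DMSO pairs. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg within each contrast). Differences are log2 ± SE from limma.

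The genes named were fixed by a rule before the data were examined: MITF, EP300 and CREBBP in every contrast; the 5 called genes with the largest difference in each direction per line and time, 12 per direction for a mean over lines and 8 for the other contrasts; and up to 4 called members of each gene list, with every pigmentation gene where that list is described. Genes named by size in a line or mean had their A-485 array beyond both DMSO arrays. Genes chosen by size also had to lie above the floor on both sides, which was added after the values below 0 were seen. Genes named outside that rule are said to be so. The 25 gene lists, written from general knowledge before the data were examined, held 581 genes, of which 531 were on the array and 504 were tested. They covered pigmentation, the MITF program, lineage factors, the MITF-low state, DNA replication, mitosis, MYC targets of ribosome biogenesis, MAP kinase output, TGF-beta and BMP signalling, senescence, the endoplasmic reticulum stress and integrated stress response, immediate early genes, p53 targets, interferon response, NF-kappaB targets, hypoxia, cholesterol synthesis, lysosomes, acetylation machinery, the BCL2 family, heat shock, fibroblast markers, keratinocyte and epithelial markers, leukocyte markers and housekeeping genes. Each list was compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over all lists of a contrast, and again with a correlation estimated per list. The rotation test fry, which asks whether a list moves on balance and does not compare it with other genes, was run as an alternative.

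In simulated data, 100 genes well above the floor were changed by a log2 of 1 and 100 by 2 among the 14130. Within a line, 85% to 91% of the smaller and 96% to 98% of the larger changes were recovered, and 8.96% to 12.6% of calls were unchanged genes. For line means 98% to 100% of both sizes were recovered. At 6 h and 24 h 10.4% and 11.7% of calls were unchanged genes, above the nominal 5%. Dim genes, as many changes as called here and a wider A-485 spread were not tested. The 11 A-485 contrasts of data with no change gave 0 calls each in limma. Over 5 draws of 6 within-line comparisons unchanged genes were 5.65% of calls with no scaling or floor and 6.28% with scaling alone. They were 8.84% with the floor alone, 8.86% with both, and 5.99% with both over genes above the floor on all arrays.

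Alternatives chosen before the data were examined were the values as deposited, arrays centred on their median, floors of 1 and 16, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, leaving out cross-hybridizing probe sets, an intensity trend with robust moderation, a 2-fold threshold, a fit to the arrays of 1 time, the replicate number as a block, an additive fit, other lines as the odd one out, estimated correlation, fry, and leaving out each array. The setting planned first, the values as deposited with a floor of 1, was kept as an alternative when it was replaced. Chosen after seeing the data were scaling to the 75th percentile, only genes above the floor on all arrays, leaving out together the 3 DMSO arrays with transcripts of another line, and, for the lists in single lines and in the differences of A375, only genes at least 2-fold above the floor on every DMSO array compared, called genes with room to fall in the text. Genes dropped by the filter and probe sets with no or several symbols were left out of the comparisons. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.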

Results

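Gene expression was measured in 3 BRAF-mutant human melanoma cell lines, SKMEL5, WM2664 and A375, after treatment with A-485 or with its solvent DMSO. A-485 is a small molecule that competes with acetyl-CoA and blocks the catalytic acetyltransferase activity of the closely related coactivators p300 (EP300) and CBP (CREBBP). Cells were collected after 6 h and 24 h. Each line and time had 2 DMSO arrays and 1 A-485 array, 18 arrays in all. The dose was labelled 3 mM for every A-485 sample, and that unit was not checked here. The series was set up to compare sensitive with resistant lines, without saying which line is which, and its title names MITF, the transcription factor that directs the melanocyte lineage.

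The number of arrays limits the precision. Replicate DMSO arrays correlated across genes at 0.990 to 0.994, and between 56.9% and 58.6% of genes lay above the floor on an array. The median SE over genes was 0.13 (log2) for a single line and time, 0.08 for a mean over the 3 lines and 0.16 for the difference of A375 from the other lines. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Every A-485 group was a single array without a replicate check of its own, and its p-values borrow the spread of the DMSO pairs. Differences below are log2, A-485 minus DMSO, ± SE.

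MITF transcript fell with A-485 in each of the 3 lines at both times. At 6 h the difference was -1.34 ± 0.08 in SKMEL5, -2.62 ± 0.08 in WM2664 and -1.13 ± 0.08 in A375 (adjusted p 5.58e-05, 2.27e-06 and 0.000132). At 24 h it was -0.50 ± 0.08, -1.51 ± 0.08 and -1.49 ± 0.08 (adjusted p 0.00264, 1.70e-05 and 2.93e-05). The mean over the lines was -1.69 ± 0.05 at 6 h and -1.17 ± 0.05 at 24 h, and the change from 6 h to 24 h was 0.53 ± 0.07 (adjusted p 0.00171). The 3 probe sets of MITF differed in size, with -1.34, -1.58 and -2.26 in SKMEL5 at 6 h and -0.50, -0.74 and -1.86 at 24 h. In WM2664 they gave -2.62, -3.20 and -0.55, then -1.51, -1.79 and -0.29, and in A375 the last of them lay at the floor. Their mean moved SKMEL5 at 24 h from -0.50 to -1.03. With the values as deposited the call in SKMEL5 at 24 h ended, at -0.64, and with a floor of 1 added those in SKMEL5 and A375 at 6 h ended too, at -1.08 and -1.10. The call of the change between times ended without either WM2664 A-485 array, where it was 0.24.

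**Figure D1:**
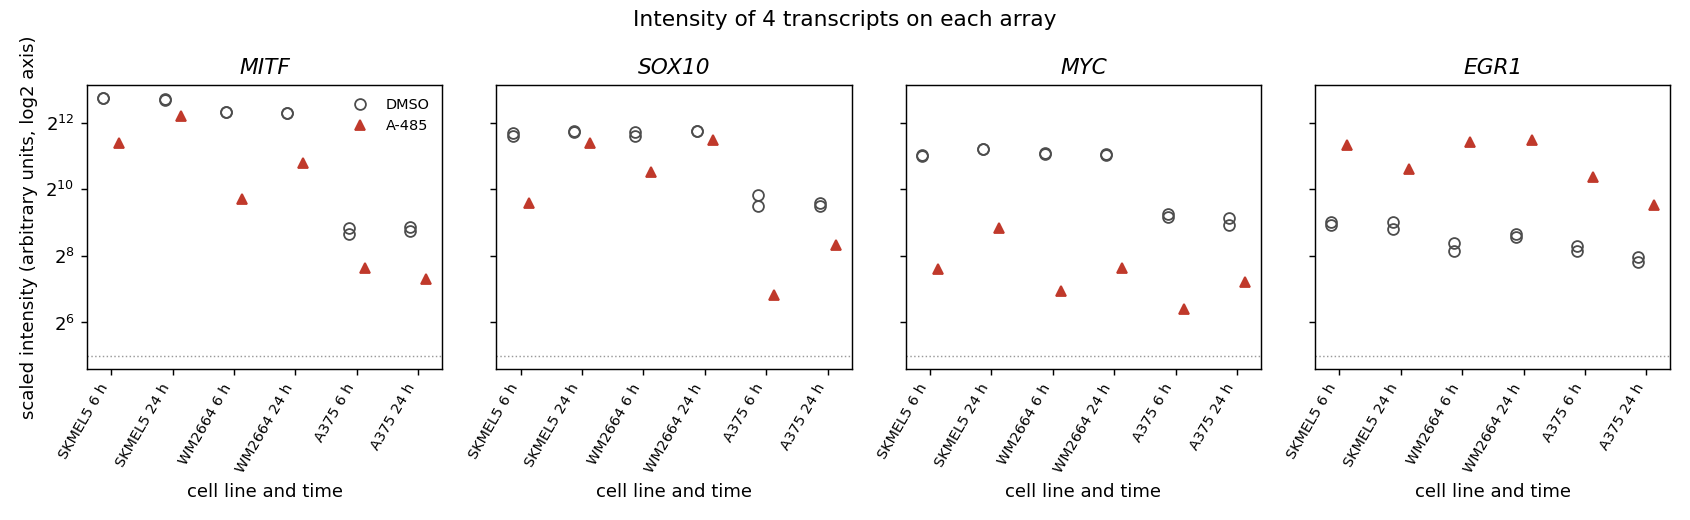
Scaled intensity (arbitrary units, log2 axis) of MITF, SOX10, MYC and EGR1 on each array, by line and time, with DMSO arrays as circles, A-485 arrays as triangles and the floor of 32 as a dotted line. MITF, SOX10 and MYC lay below both DMSO arrays and EGR1 above them in the 3 lines at 6 h.

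The transcripts of the targets themselves were higher where they were called. CREBBP rose by 0.72 ± 0.15 in SKMEL5 and 0.65 ± 0.15 in WM2664 at 6 h (adjusted p 0.0147 and 0.0191) and by 0.84 and 0.88 at 24 h. In A375 the differences were 0.03 ± 0.15 and 0.38 ± 0.15 (adjusted p 1 and 0.147). These values are from 1 probe set of CREBBP, and others disagreed: at 6 h the next gave 0.61, 0.39 and 0.80 in SKMEL5, WM2664 and A375, and another -0.06, 0.79 and 0.29. EP300 rose in SKMEL5 and WM2664 at 24 h by 0.59 and 0.60 (adjusted p 0.0472 and 0.0491) and stood at 0.54 ± 0.19, 0.55 ± 0.19 and 0.02 ± 0.19 at 6 h (adjusted p 0.0917, 0.0746 and 1). The difference of A375 from the other lines was not called for CREBBP (-0.65 ± 0.19, adjusted p 0.0677, at 6 h and -0.48 ± 0.19, adjusted p 0.112, at 24 h) or for EP300 (adjusted p 0.216 and 0.496). The calls ended with the values as deposited for CREBBP in both lines at both times, with 1.06 and 1.10 at 6 h and 0.79 and 1.16 at 24 h. At 6 h they also ended with the mean of its probe sets (0.32) or without SKMEL5 DMSO 6 h replicate 1 in SKMEL5 (0.68), and without WM2664 DMSO 6 h replicate 2 in WM2664 (0.62). The 24 h calls of EP300 ended, at 0.59 and 0.60, without any 1 DMSO array other than those of SKMEL5 at 24 h, with no filter on dim genes and with a floor of 1 or 16.

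Averaged over the lines, 6 h of A-485 lowered MYC, the growth-promoting transcription factor, by more than any other gene named by size, with a difference of -3.44 ± 0.05 (adjusted p 6.79e-08). Regulators of the neural crest and melanocyte lineage fell with it, among them SOX10 (-2.01 ± 0.07), SNAI2 (-2.20 ± 0.11) and the receptor ERBB3 (-2.50 ± 0.06). The pseudokinase TRIB2 (-2.08 ± 0.04), the corepressor TLE1 (-1.96 ± 0.05), the kinase PLK2 (-1.95 ± 0.06), the adaptor BCAR3 (-1.94 ± 0.04), ZNF703 (-2.60 ± 0.24), EVA1A (-2.47 ± 0.07) and LRATD2 (-2.25 ± 0.03) also fell. Genes that rose included the immediate early gene EGR1 (2.55 ± 0.07), CCN2, which encodes a matricellular protein (1.70 ± 0.13), GCH1, an enzyme of tetrahydrobiopterin synthesis (1.65 ± 0.06), GRHL1 (1.45 ± 0.16), SERTAD1 (1.34 ± 0.12), IRF7 (1.26 ± 0.09) and ARL6 (1.22 ± 0.06). In at least 1 line TRIB2, ZNF703 and EVA1A fell to within 2-fold of the floor and GRHL1 and IRF7 rose from there, so their sizes are not exact. ZNF703 was -1.76 without SKMEL5 A-485 6 h replicate 1 and -3.63 without A375 A-485 6 h replicate 1. In all, 5238 of 14130 genes were called, 3096 higher and 2142 lower, of which 305 differed at least 2-fold, 53 higher and 252 lower. In each of the 3 lines, 354 genes were called higher and 315 lower. With the values as deposited and a floor of 1 the count was 2741. An additive fit of line and treatment to the 9 arrays of 6 h, which puts the spread between lines in the error, gave 2777.

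In SKMEL5 at 6 h, A-485 lowered ZNF703 (-4.26 ± 0.41), MYC (-3.40 ± 0.08), the hyaluronan synthase HAS2 (-3.26 ± 0.17), the transcription factor IRF4 (-3.14 ± 0.16) and the ubiquitin ligase TRIM63 (-2.83 ± 0.08). It raised the MYC antagonist MXD1 (2.55 ± 0.15), EGR1 (2.35 ± 0.13), the nuclear receptor NR4A2 (2.14 ± 0.13) and PIK3IP1 (1.91 ± 0.35). SETD4 was 1.99 ± 0.26 at its brightest probe set and -0.016 when cross-hybridizing probe sets were left out. In all, 3085 genes were called, 1767 higher and 1318 lower, and with the values as deposited and a floor of 1 the count was 114 and TRIM63 was not called. ZNF703 fell to within 2-fold of the floor, and PIK3IP1 and SETD4 rose from there. In WM2664 at 6 h, MYC (-4.12 ± 0.08), the glycosyltransferase GALNT3 (-3.92 ± 0.07), NFATC2 (-3.91 ± 0.16), the ATP receptor P2RX7 (-3.83 ± 0.04) and TBX2 (-3.76 ± 0.23) fell. EGR1 (3.15 ± 0.13), the cyclooxygenase gene PTGS2 (2.46 ± 0.19), CCN2 (2.40 ± 0.23), GCH1 (2.29 ± 0.11) and IRF7 (1.99 ± 0.16) rose. Calls numbered 3607, 2097 higher and 1510 lower, against 511 with the values as deposited and a floor of 1, where P2RX7 and TBX2 were not called. GALNT3 fell to near the floor, and PTGS2 and IRF7 rose from within 2-fold of it. WM2664 DMSO 6 h replicate 1 had an excess at genes high in SKMEL5, with a median of 1.76% of the SKMEL5 level. Over 46 genes high in SKMEL5 and low in WM2664, 9 were called lower and 3 higher with that array and 6 and 4 without it, and their median of -0.39 became 0 without it.

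In A375 at 6 h the largest falls among the genes named by size were those of the Wnt antagonist DKK1 (-4.25 ± 0.21), the adhesion protein AMIGO2 (-3.55 ± 0.35), the activin subunit INHBA (-3.36 ± 0.06), the transcription factor PRDM1 (-3.29 ± 0.11) and the insulin receptor substrate IRS1 (-3.28 ± 0.10). EGR1 (2.15 ± 0.13), LMO2 (1.60 ± 0.27), CCN2 (1.46 ± 0.23), ELOVL7 (1.40 ± 0.10) and MXD1 (1.37 ± 0.15) rose. MYC fell here too (-2.79 ± 0.08). PRDM1 (scaled intensity 32.3) and IRS1 ended within 2-fold of the floor, so these falls are not exact, and LMO2 and ELOVL7 rose from within 2-fold of it. In all, 1798 genes were called, 828 higher and 970 lower, of which 384 differed at least 2-fold, 53 higher and 331 lower. Without scaling between arrays the count was 425, without the 3 DMSO arrays that carried transcripts of another line it was 1163, and with the values as deposited and a floor of 1 it was 177, with AMIGO2, INHBA, PRDM1, IRS1, LMO2, CCN2, ELOVL7 and MXD1 not called. SKMEL5 and WM2664 shared 1150 higher and 798 lower genes at 6 h against 262 and 141 for independent lists. SKMEL5 and A375 shared 423 and 388 against 104 and 90.5, and WM2664 and A375 shared 466 and 459 against 123 and 104. The lines share no control arrays, but share 1 spread per gene, which can raise the overlap.

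The lineage factors, mostly transcription factors with the receptor ERBB3, the cadherin CDH19 and S100B, were lowered at 6 h. Of 17 measured in SKMEL5, 12 fell (adjusted over the list alone, 1 rose and 13 fell). In WM2664 14 fell (adjusted over the list alone, 1 rose and 15 fell), and in A375 1 rose and 9 fell (adjusted over the list alone, 2 rose and 9 fell). The medians were -1.0, -1.50 and -0.47. TFAP2A, a regulator of melanocyte genes, fell in the 3 lines (-1.77, -1.72 and -1.10). SOX10 fell in A375 (-2.85, where its other probe set gave -0.91), and TFAP2B fell in WM2664 to near the floor (-2.65). Relative to other genes the list was called in camera in each line (adjusted p 2.05e-09, 2.11e-12 and 8.81e-06). The A375 call was lost with an estimated correlation (adjusted p = 0.0562 with an estimated correlation), where the other calls kept adjusted p of 0.014 and 0.0164. Over the 12 members with room to fall in A375 it held (8 lower, camera adjusted p 1.25e-06, or 0.0118 with an estimated correlation).

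The genes of the MITF program, a list of 49 genes known to be bound or driven by MITF, fell in SKMEL5 and WM2664 at 6 h. In SKMEL5 30 fell and 19 were not called (adjusted over the list alone, 36 fell). In WM2664 32 fell and 17 were not called (adjusted over the list alone, 1 rose and 32 fell). TRIM63 (-2.83 and -2.53), LZTS1 (-2.02 and -2.93) and GALNT3 (-2.26 and -3.92) were among the members that fell in both. PPARGC1A, a coactivator of mitochondrial genes, fell in WM2664 to the floor (at least as far as -3.13). The medians were -0.76 and -0.70 (camera adjusted p 6.63e-22 and 1.30e-16, or 0.0022 and 0.00483 with an estimated correlation). In A375 2 rose and 5 fell, and as many adjusted over the list alone, and the list was not called (adjusted p 0.422), but 18 members were at the floor on all A375 arrays of that time and could not fall. The difference of A375 from the other lines was called for 24 members, all higher (adjusted over the list alone, 32), a count that the floor inflates. Of the 20 members with room to fall in the 3 lines, 7 were higher and 13 not called (adjusted over the list alone, 10 higher), with a median of 0.44 (camera adjusted p 3.87e-07, or 0.0189 with an estimated correlation). In DMSO these genes were low in A375, with 47 of 49 below the other lines and a median of -2.66 (camera adjusted p 1.79e-16, or 0.00495 with an estimated correlation).

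Among 15 pigmentation genes, of enzymes and structural proteins of melanosomes, in SKMEL5 at 6 h 6 fell, and as many adjusted over the list alone. In WM2664 6 fell (adjusted over the list alone, 8 fell). MLPH (-0.93 and -1.95), HPS4 (-1.93 and -0.64), RAB38 (-0.61 and -0.90) and SLC45A2 (-0.58 and -0.80) fell in both. PMEL (-0.08 and -0.09), GPNMB (-0.15 and -0.10, other set -0.53 and -0.41) and OCA2 (-0.93 and 0.24) were not called in either line. Without scaling RAB38 (-0.36 and -0.50) and SLC45A2 (-0.26 and -0.29) were not called in either line, MLPH (-0.59) not in SKMEL5 and HPS4 (-0.15) not in WM2664. The SLC45A2 calls also ended (-0.58 and -0.76) without the 3 DMSO arrays that carried transcripts of another line. The camera adjusted p were 9.30e-05 and 7.61e-05 and were lost with an estimated correlation (adjusted p = 0.139 and 0.148 with an estimated correlation). In A375 2 fell, and as many adjusted over the list alone. That list was called too (camera adjusted p 0.00261, lost at adjusted p = 0.227 with an estimated correlation). The array of A375 DMSO 6 h replicate 1 stood apart for these genes: its scaled intensity was 222.9 for PMEL, 263.9 for MLANA, 178.5 for TYRP1 and 62.1 for TYR, against 41.0, 32, 32 and 32 in the other DMSO array of A375 at 6 h. That array widens the spread of these genes in every contrast. Without it 8 members fell in SKMEL5 and 10 in WM2664 (adjusted p = 0.0300 and 0.0263 with an estimated correlation), and A375 had 2 lower, a median of -0.04 and no list call (camera adjusted p 0.314).

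The MITF-low state, a list of 27 genes known to be high in melanoma cells with little MITF, fell in A375. There 1 rose, 17 fell and 9 were not called (adjusted over the list alone, 1 rose and 20 fell), with a median of -0.72 (camera adjusted p 4.03e-15, or 0.00223 with an estimated correlation). DKK1 (-4.25), INHBA (-3.36), the kinase NUAK1 (-2.38) and the cytokine IL6 (-2.29, to near the floor) fell. In SKMEL5 5 rose and 5 fell (adjusted over the list alone, 7 rose and 6 fell). In WM2664 4 rose and 6 fell, and as many adjusted over the list alone. Neither list was called (adjusted p 0.74 and 0.107), and over the 16 members with room to fall in WM2664 the call (camera adjusted p 0.0219) was lost (adjusted p = 0.102 with an estimated correlation). The difference of A375 from the other lines was called for 1 member higher and 13 lower (adjusted over the list alone, 1 and 15), but 8 members were at the floor in a line. Of the 12 with room to fall in the 3 lines, 1 was higher and 5 lower (adjusted over the list alone, 1 and 6), and that call (camera adjusted p 0.00769) was lost (adjusted p = 0.0755 with an estimated correlation).

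Among MAP kinase output genes, a list meant to follow the activity of the BRAF pathway, more fell than rose in the 3 lines at 6 h. Of 20 measured in SKMEL5, 1 rose and 12 fell, and as many adjusted over the list alone. In WM2664 2 rose and 11 fell (adjusted over the list alone, 2 rose and 12 fell). In A375 12 fell, and as many adjusted over the list alone. The list was called in each line (camera adjusted p 1.82e-08, 1.39e-05 and 6.66e-12, or 0.00803, 0.0164 and 0.00277 with an estimated correlation). The phosphatase DUSP4 (-1.13, -1.03 and -2.07) and PLK2 (-1.74, -1.89 and -2.23) fell in each, and PHLDA1 and the inhibitor SPRY2 were at -1.74 and -1.26 in A375.

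Among 16 targets of TGF-beta and BMP signalling at 6 h, 2 rose and 7 fell (adjusted over the list alone, 3 rose and 7 fell) in SKMEL5. In WM2664 2 rose and 5 fell, and as many adjusted over the list alone, and in A375 1 rose and 9 fell (adjusted over the list alone, 1 rose and 10 fell). The feedback regulators PMEPA1 and BAMBI fell in each line, with PMEPA1 at the floor in SKMEL5 and WM2664 (at least as far as -1.79 and -3.06) and at -2.77 in A375, and BAMBI at -2.0, -2.71 and -1.09. That list was called in each line (camera adjusted p 0.00394, 0.00528 and 2.06e-06), and the SKMEL5 and WM2664 calls were lost (adjusted p = 0.139 and 0.148 with an estimated correlation) while the A375 call held (0.0353). Among 17 senescence-associated genes in A375, 8 fell (adjusted over the list alone, 9 fell), including the cytokines CXCL1 (-1.66) and IL1A (at the floor, at least as far as -0.96), and the list was called (camera adjusted p 7.61e-07, or 0.0353 with an estimated correlation). Over the 15 members with room to fall that call was lost (adjusted p = 0.0721 with an estimated correlation). In SKMEL5 3 rose and 4 fell (adjusted over the list alone, 3 rose and 5 fell). In WM2664 2 rose and 4 fell (adjusted over the list alone, 3 rose and 4 fell), and neither list was called (adjusted p 0.467 and 0.255).

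Of 25 genes, MYC and its targets of ribosome biogenesis, 12 fell in SKMEL5 at 6 h (adjusted over the list alone, 14 fell). In WM2664 2 rose and 10 fell, and as many adjusted over the list alone. The gene of the nucleolar protein NOP16 fell in both (-0.88 and -1.10). The medians were -0.33 and -0.19 (camera adjusted p 4.54e-09 and 7.61e-05), and without scaling between arrays they were 0.02 and 0.22. The SKMEL5 call held with an estimated correlation (0.0128) and the WM2664 call was lost (adjusted p = 0.056 with an estimated correlation). In A375 1 fell, MYC itself (-2.79), and as many adjusted over the list alone. The list was not called there (adjusted p 0.593).

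Of 38 mitosis genes measured in SKMEL5 at 6 h, 19 rose (adjusted over the list alone, 25 rose and 1 fell). In WM2664 16 rose and 1 fell (adjusted over the list alone, 21 rose and 1 fell). The medians were 0.31 and 0.33. The mitotic kinase TTK rose by 0.97 in SKMEL5 and the topoisomerase TOP2A by 0.86 and 0.49. The SKMEL5 call of this list held (camera adjusted p 6.86e-07, or 0.0128 with an estimated correlation) and the WM2664 call was lost (camera adjusted p 0.000387, and adjusted p = 0.0533 with an estimated correlation). In A375 at 6 h, limma called 0 of the 38 mitosis genes, and 2 were higher and 2 lower at an unadjusted p under 0.05.

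Of 39 DNA replication genes measured in WM2664 at 6 h, 9 rose (adjusted over the list alone, 8 rose). In A375 9 rose (adjusted over the list alone, 13 rose), and in SKMEL5 6 rose and 2 fell, and as many adjusted over the list alone. The cyclin CCNE2 rose by 0.61, 0.86 and 0.70 in SKMEL5, WM2664 and A375. The list calls in WM2664 and A375 (camera adjusted p 0.00528 and 8.81e-06) were lost with an estimated correlation (adjusted p = 0.284 and 0.147 with an estimated correlation), and SKMEL5 had none (adjusted p 0.368).

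After 24 h, the mean over the lines was lowest for the adhesion receptor ADGRG1 (-2.76 ± 0.06) and MYC (-2.53 ± 0.05, adjusted p 1.65e-07) among the genes named by size. LRATD2 (-2.48 ± 0.03), the metalloproteinase inhibitor TIMP3 (-2.25 ± 0.11), VEPH1 (-2.19 ± 0.05), the amino acid transporter SLC7A5 (-2.17 ± 0.11), the protease PRSS23 (-2.09 ± 0.06), SNAI2 (-2.09 ± 0.11), CYB5R2 (-2.06 ± 0.04), TNFRSF21 (-1.95 ± 0.07) and the mitotic kinase AURKB (-1.94 ± 0.11) also fell. CCN2 (2.21 ± 0.13) and EGR1 (2.06 ± 0.07) again had the largest rises among the genes named by size. They were followed by ICA1L (1.5 ± 0.10), the metallothionein MT1F (1.36 ± 0.07), SERTAD1 (1.32 ± 0.12), the coagulation inhibitor TFPI (1.32 ± 0.13), SAMD9 (1.3 ± 0.22) and GCH1 (1.29 ± 0.06). In at least 1 line SNAI2, CYB5R2 and AURKB fell to within 2-fold of the floor and ICA1L and TFPI rose from there. ADGRG1 was -3.65 without SKMEL5 A-485 24 h replicate 1 and -1.92 without WM2664 A-485 24 h replicate 1, AURKB -0.90 and CCN2 1.48 without them in that order. Without A375 A-485 24 h replicate 1, VEPH1 and SLC7A5 were -2.89, AURKB -2.69 and CCN2 3.13. In all, 6576 genes were called, 3679 higher and 2897 lower, with 402 differing at least 2-fold, 75 higher and 327 lower. In each of the 3 lines, 522 genes were called higher and 290 lower. The count was 2915 without scaling between arrays, 1662 with the values as deposited and a floor of 1, and 2264 with an additive fit of line and treatment.

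In SKMEL5 at 24 h, HAS2 (-4.75 ± 0.17), TRPM1, a melanocyte channel gene (-4.66 ± 0.11), GALNT3 (-4.09 ± 0.07), AURKB (-4.02 ± 0.19) and the centromere chaperone HJURP (-3.92 ± 0.08) fell. The histone gene H2BC4 (2.76 ± 0.33), NR4A2 (2.73 ± 0.13), CCN2 (2.60 ± 0.23), ALDH5A1 (2.40 ± 0.22) and the sulfite oxidase SUOX (2.27 ± 0.24) rose. HAS2, TRPM1, AURKB and HJURP fell to within 2-fold of the floor, and H2BC4 and ALDH5A1 rose from there. Calls numbered 4981, 2844 higher and 2137 lower.

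In WM2664 at 24 h, PI15 (-4.57 ± 0.10), ADGRG1 (-4.43 ± 0.10), P2RX7 (-4.33 ± 0.04), LINC00520 (-4.14 ± 0.08) and CCN3 (-4.02 ± 0.27) fell. CCN2 (3.66 ± 0.23), the receptor FGFR1 (3.31 ± 0.17), TMT1B (3.14 ± 0.11), EGR1 (2.84 ± 0.13) and SEC14L4 (2.57 ± 0.28) rose. P2RX7 and LINC00520 (scaled intensity 32.5 with A-485) fell to within 2-fold of the floor. Calls numbered 4555, 2487 higher and 2068 lower. WM2664 DMSO 24 h replicate 2 had an excess at genes high in A375, with a median of 0.758% of the A375 level. In A375, the carboxypeptidase CPA4 (-4.62 ± 0.34), the growth factor binding protein IGFBP3 (-4.02 ± 0.05), SERPINB7 (-3.74 ± 0.05), the matrix link protein HAPLN1 (-3.70 ± 0.10) and the activin antagonist FST (-3.52 ± 0.15) fell. There, SYT7 (1.86 ± 0.44), the metallothionein MT1E (1.81 ± 0.09), UNC119 (1.78 ± 0.39), DLK2 (1.65 ± 0.12) and EGR1 (1.64 ± 0.13) rose. In A375, CPA4, IGFBP3 and HAPLN1 fell to within 2-fold of the floor, and SYT7, UNC119 and DLK2 rose from there. Calls numbered 2465, 1279 higher and 1186 lower.

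Without scaling between arrays, the 24 h counts were 1228 in SKMEL5, 1339 in WM2664 and 632 in A375, and with the values as deposited and a floor of 1 they were 657, 503 and 237. In the latter setting H2BC4 and TRPM1 in SKMEL5, P2RX7 and SEC14L4 in WM2664, and HAPLN1, FST, SYT7, UNC119 and EGR1 in A375 were not called. Calls also ended without A375 DMSO 24 h replicate 2 for SYT7 (1.60) and UNC119 (1.90) and without replicate 1 for UNC119 (1.65). SKMEL5 and WM2664 shared 1514 higher and 1183 lower genes at 24 h, against 501 and 313 for independent lists. A375 shared 690 and 408 with SKMEL5, against 257 and 179, and 645 and 473 with WM2664, against 225 and 174. Across genes, which are not independent replicates, the responses of SKMEL5 and WM2664 correlated at 0.615 at 6 h and 0.567 at 24 h, and those of A375 with them at 0.357 and 0.402 at 6 h and 0.207 and 0.285 at 24 h.

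Mitosis genes fell at 24 h in SKMEL5 and WM2664. Of 38 measured in SKMEL5, 36 fell (adjusted over the list alone, 37 fell). In WM2664 33 fell (adjusted over the list alone, 36 fell). The medians were -1.86 and -0.52. The cell cycle kinase CDK1 (-3.17 and -0.69) and the centromere histone CENPA (-3.06, to near the floor, and -0.89) fell in both. Both list calls held (camera adjusted p 1.21e-30 and 1.97e-14, or 0.000615 and 0.00284 with an estimated correlation). In A375 3 rose and 2 fell (adjusted over the list alone, 2 rose and 2 fell), with a median of 0.08 and no list call (adjusted p 0.56). The difference of A375 from the other lines was called for 37 of 38 members, all higher (adjusted over the list alone, 38), with a median of 1.31, 0.60 without SKMEL5 A-485 24 h replicate 1 and 1.96 without WM2664 A-485 24 h replicate 1 (camera adjusted p 8.02e-28, or 0.000816 with an estimated correlation).

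Of the 39 DNA replication genes in SKMEL5 at 24 h, 37 fell, and as many adjusted over the list alone. The median there was -2.03, with the replication factor DTL at -3.54, near the floor, the flap endonuclease FEN1 at -2.81 and the ribonucleotide reductase subunit RRM2 at -3.08 (camera adjusted p 7.82e-30, or 0.00464 with an estimated correlation). In WM2664 1 rose and 21 fell (adjusted over the list alone, 1 rose and 23 fell). The median was -0.40, with the helicase subunit MCM4 at -0.65. That list call (camera adjusted p 1.47e-09) was lost (adjusted p = 0.0653 with an estimated correlation). In A375 8 rose and 1 fell, and as many adjusted over the list alone, with no list call (adjusted p 0.139), and the difference from the other lines was called for 34 members, all higher (adjusted over the list alone, 35; camera adjusted p 3.65e-26, or 0.00649 with an estimated correlation).

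**Figure D2:**
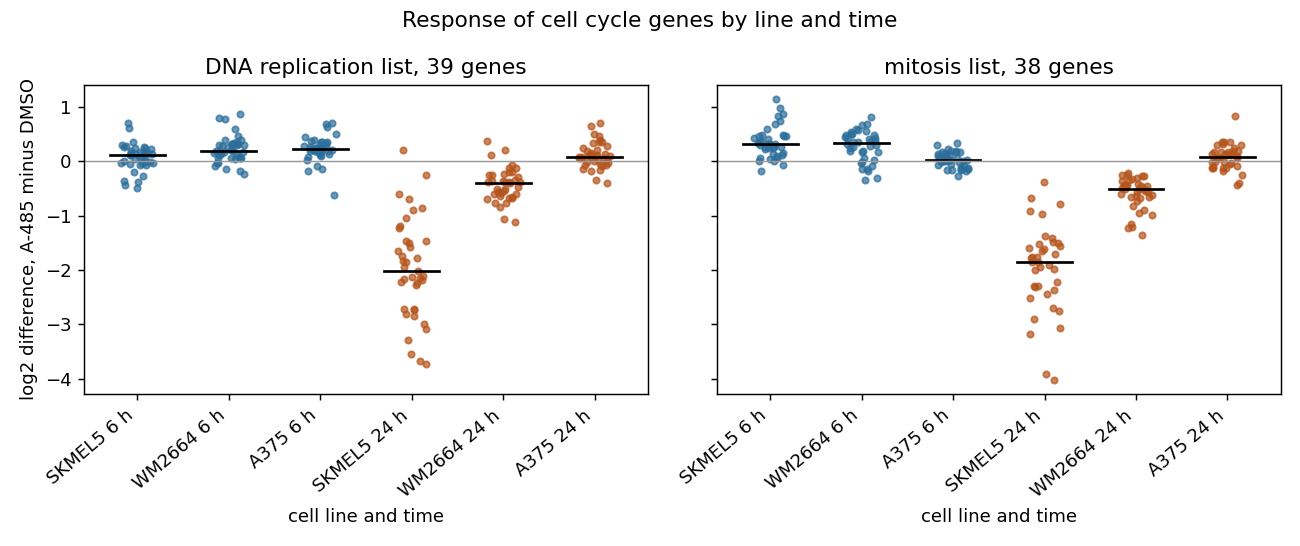
Log2 difference, A-485 minus DMSO, of each measured gene of the DNA replication (39) and mitosis (38) lists by line and time, with 1 point per gene and a black bar at the median. The medians at 24 h were -2.03 and -1.86 in SKMEL5, -0.40 and -0.52 in WM2664, and 0.08 and 0.08 in A375.

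The MITF program was also lowered at 24 h in SKMEL5 and WM2664. Of its 49 genes in SKMEL5, 36 fell (adjusted over the list alone, 40 fell). In WM2664 1 rose and 35 fell (adjusted over the list alone, 2 rose and 36 fell). The medians were -0.85 and -1.04. TRIM63 (-3.18 and, near the floor, -3.69), LZTS1 (-2.25 and -2.87) and TRPM1 (-4.66 and, at the floor with A-485, at least as far as -5.13) fell in both. The list calls held (camera adjusted p 2.64e-17 and 2.13e-17, or 0.00233 and 0.00284 with an estimated correlation). In A375 4 rose and 4 fell, and as many adjusted over the list alone, with no list call (adjusted p 0.675) and 17 members at the floor on all A375 arrays of that time. The difference from the other lines was called for 36 members, all higher (adjusted over the list alone, 38), again inflated by the floor. Of the 20 members with room to fall, 13 were higher and 7 not called (adjusted over the list alone, 14 higher), with a median of 0.85 (camera adjusted p 5.27e-07, or 0.00786 with an estimated correlation). The lineage factors had 3 higher and 7 lower in SKMEL5, 3 and 9 in WM2664, and 2 and 8 in A375 (adjusted over the list alone, 3 and 8, 4 and 9, and 4 and 9). ERBB3 fell in each line, at -0.94, -2.0 and, near the floor, -2.50, as did TFAP2A, at -0.86, -0.93 and -1.15. Their list calls in WM2664 and A375 (camera adjusted p 0.00172 and 0.000753) were lost (adjusted p = 0.135 and 0.139 with an estimated correlation), and SKMEL5 had none (adjusted p 0.155).

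At 24 h, of the 15 pigmentation genes in SKMEL5, 9 fell, and as many adjusted over the list alone. In WM2664 11 fell, and as many adjusted over the list alone. The medians were -0.56 and -1.35. SLC45A2 (-1.81 and -2.88), GPR143 (-1.34 and -2.41), TSPAN10 (-2.19 and, near the floor, -2.86) and MLPH (-1.27 and -2.37) fell in both. The list calls (camera adjusted p 1.93e-05 and 9.88e-09) were lost (adjusted p = 0.119 and 0.0611 with an estimated correlation). Without A375 DMSO 6 h replicate 1, the array with raised pigment transcripts, 12 members fell in SKMEL5 and 14 in WM2664 (adjusted p = 0.0223 and 0.0114 with an estimated correlation). In WM2664 TYRP1 was then -4.02 ± 0.04, MLANA -2.46 ± 0.07 and TYR -0.63 ± 0.04. With that array MLANA and TYR were not called in WM2664 (adjusted p 0.103 and 0.182). The brightest probe set of a gene sometimes fell less than another. In WM2664 at 24 h MLANA had -2.46 against -4.30, GPNMB -0.40 against -1.50 and TYR -0.63 against -2.88 and -0.70. In A375 1 rose and 3 fell, and as many adjusted over the list alone, with a median of 0.00 and no list call (adjusted p 0.588).

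The MITF-low state was also lowered in A375 at 24 h. Of its 27 genes, 2 rose and 17 fell (adjusted over the list alone, 2 rose and 19 fell). The median was -0.80 (camera adjusted p 4.66e-13, or 0.00339 with an estimated correlation). The thrombospondin THBS1 (-2.94), the collagen COL13A1 (-3.37, near the floor), INHBA (-2.22) and NUAK1 (-1.70) fell. In SKMEL5 6 rose and 6 fell, and as many adjusted over the list alone. In WM2664 5 rose and 5 fell (adjusted over the list alone, 5 rose and 6 fell), and neither list was called (adjusted p 0.722 and 0.863). The difference of A375 was called for 1 member higher and 17 lower (adjusted over the list alone, 2 and 21), with 11 members at the floor in a line. Of the 11 with room to fall, 1 was higher and 5 lower (adjusted over the list alone, 2 and 6), and that call (camera adjusted p 0.0244) was lost (adjusted p = 0.0833 with an estimated correlation). The senescence list had 2 higher and 7 lower in A375 (adjusted over the list alone, 2 and 8). IGFBP3 and CDKN1C (at the floor, at least as far as -2.91) fell. The call (camera adjusted p 0.000151) was lost (adjusted p = 0.0916 with an estimated correlation). The list was not called in SKMEL5 (3 and 4, 4 and 5 over the list alone, adjusted p 0.465) or WM2664 (1 and 6 in both, adjusted p 0.168). Genes were not sorted by direction in senescence, so the list does not test it.

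Among the 25 MYC targets of ribosome biogenesis in SKMEL5 at 24 h, 22 fell (adjusted over the list alone, 24 fell). In WM2664 16 fell (adjusted over the list alone, 1 rose and 18 fell), and in A375 8 fell (adjusted over the list alone, 13 fell). The medians were -0.81, -0.49 and -0.20. NOP16 (-1.10, -1.12 and -0.34) fell in each, as did MYC (-2.37, -3.40 and -1.81), which is counted in the list. The spermidine synthase SRM fell in SKMEL5 and WM2664 (-1.26 and -0.89). The list calls held (camera adjusted p 2.80e-13, 7.68e-09 and 2.86e-06, or 0.00464, 0.019 and 0.0415 with an estimated correlation), but against only genes with room to fall, all 25 members among them, the A375 call was lost (adjusted p = 0.0624 with an estimated correlation).

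MAP kinase output genes at 24 h had 2 higher and 10 lower in SKMEL5, 5 and 7 in WM2664 and 8 lower in A375 (adjusted over the list alone, 3 and 11, 5 and 7, and 9 lower), with DUSP4 and SPRY2 at -1.53 and -0.90 in A375. That list was called in A375 (camera adjusted p 0.000151, or 0.0415 with an estimated correlation), a call lost over the 17 members with room to fall (adjusted p = 0.0530 with an estimated correlation), not in WM2664 (adjusted p 0.405), and its SKMEL5 call (0.00443) was lost (adjusted p = 0.0624 with an estimated correlation). For the 16 TGF-beta and BMP targets the counts higher and lower were 4 and 5, 2 and 7, and 2 and 7 (adjusted over the list alone, 4 and 5, 2 and 7, and 3 and 9). The SKMEL5 and WM2664 lists were not called (adjusted p 0.722 and 0.0951). The A375 call (camera adjusted p 0.014) was lost (adjusted p = 0.187 with an estimated correlation), its median of -0.47 turning to 0.17 over genes above the floor on all arrays.

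**Figure D3:**
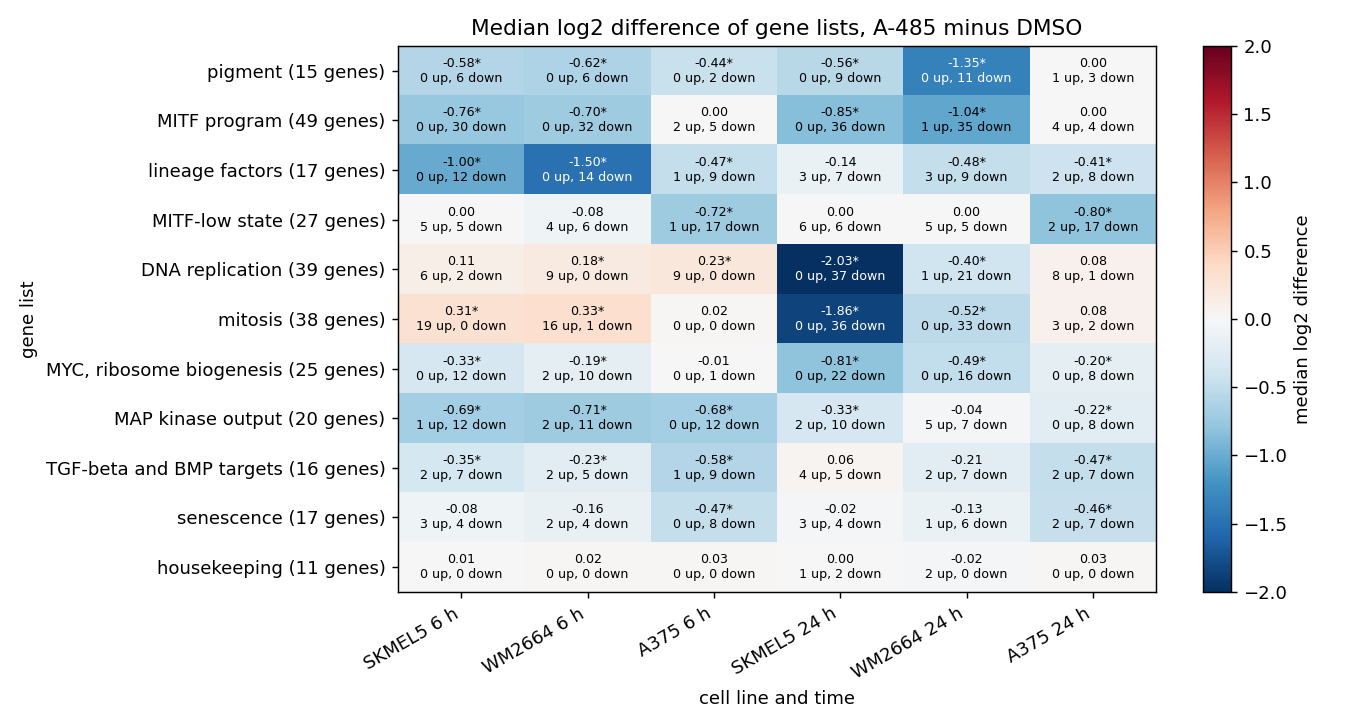
Median log2 difference, A-485 minus DMSO, of 11 gene lists in each line at each time, as a heat map with the numbers of genes called higher and lower in each cell and a star where camera called the list with a preset correlation. The median of the MITF program was -0.76 and -0.70 in SKMEL5 and WM2664 at 6 h and 0.00 in A375, and the median of the MITF-low state was -0.72 in A375 at 6 h.

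The response of A375, the line with the lowest MITF transcript of the 3, was tested against the mean of the other lines. At 6 h the response of A375 was lower for the Wnt ligand WNT5A (-2.97 ± 0.37), AJUBA (-2.76 ± 0.19), the cytokine LIF (-2.43 ± 0.18), FOSL2 (-2.09 ± 0.25), ZBTB38 (-2.01 ± 0.07), DDIT4 (-1.87 ± 0.23), TNFRSF1A (-1.75 ± 0.11) and the cell cycle inhibitor CDKN1A (-1.66 ± 0.08). It was higher for ZNF703 (3.09 ± 0.51), LZTS1 (2.39 ± 0.10), CDK5R1 (1.91 ± 0.16), VEPH1 (1.82 ± 0.11), RIPK4 (1.81 ± 0.10), PIK3R3 (1.80 ± 0.13) and HEY1 (1.79 ± 0.10). LZTS1 and ZNF703 had little room to fall in A375, where DMSO levels of LZTS1 were 43.2 and 42.8 and those of ZNF703 77.6 and 39.9, so the floor sets part of these differences. WNT5A lay within 2-fold of the floor in WM2664 in DMSO, and LIF, RIPK4 and HEY1 did in A375 with A-485. Without SKMEL5 A-485 6 h replicate 1 the difference was 1.07 for PIK3R3 and 2.46 for ZNF703, and without WM2664 A-485 6 h replicate 1 it was 2.54 and 3.73. MITF fell less in A375 at 6 h (0.85 ± 0.10, adjusted p 0.00179) and more at 24 h (-0.49 ± 0.10, adjusted p 0.0108). For MITF the 6 h call ended without WM2664 A-485 6 h replicate 1 (0.21) and without scaling (0.51), and the 24 h value was 0.017 without SKMEL5 A-485 24 h replicate 1 and 0.047 with the mean of its probe sets, 1 of which lay at the floor on all A375 arrays. With the mean of the other 2 it was -0.47 ± 0.11 (adjusted p 0.0195). Without SKMEL5 A-485 6 h replicate 1 the 6 h value was 1.49. The pigment list had 4 members higher and 1 lower at 6 h (camera adjusted p 0.0742) and 9 higher at 24 h (3.85e-06, or 0.0941 with an estimated correlation), and without A375 DMSO 6 h replicate 1 there were 8 and 13 higher. The floor inflates these counts, since 4 and 5 members were then at the floor in A375. Of the 7 with room to fall in the 3 lines, 4 and 6 were higher and the others not called without that array (adjusted over the list alone, 4 higher and 1 lower, and 6 higher). Their 6 h call (camera adjusted p 0.00829) was lost (adjusted p = 0.112 with an estimated correlation) and their 24 h call held (2.68e-05, or 0.0322 with an estimated correlation).

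At 24 h the response of A375 was lower for CPA4 (-4.76 ± 0.41), the semaphorin SEMA3C (-3.37 ± 0.17), the cadherin CDH19 (-3.35 ± 0.21), IGFBP3 (-3.16 ± 0.06), THBS1 (-2.86 ± 0.09) and CCN2 (-2.76 ± 0.28). It was higher for CHAC1, a glutathione-degrading enzyme (3.62 ± 0.68), CPN1 (3.30 ± 0.29), RMI2 (2.59 ± 0.19), the growth hormone receptor GHR (2.58 ± 0.14), the replication licensing factor CDC6 (2.55 ± 0.10) and the thiamine transporter SLC19A2 (2.29 ± 0.07). CPA4 lay within 2-fold of the floor in DMSO in both other lines and THBS1 in SKMEL5, so little fall could be seen there. SEMA3C, CDH19 and IGFBP3 ended within 2-fold of the floor in A375, CDC6 in SKMEL5 and CHAC1 in WM2664, and CPN1 started there in A375. CDC6 was 0.99 and SEMA3C -3.99 without SKMEL5 A-485 24 h replicate 1, and 4.11 and -2.75 without WM2664 A-485 24 h replicate 1. CHAC1 was 2.79 and 4.44 without A375 DMSO 24 h replicate 1 and 2.

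In all, 1684 genes differed at 6 h, 791 higher and 893 lower, and 3430 at 24 h, 1714 higher and 1716 lower. Without scaling between arrays the counts were 398 and 801, with the values as deposited and a floor of 1 they were 51 and 201, with MITF and CHAC1 among the genes not called at 24 h, and over genes above the floor on all arrays they were 798 and 2222. The lineage factors had 8 members higher and 1 lower at 6 h (camera adjusted p 7.01e-06), a call lost with an estimated correlation (adjusted p = 0.0521 with an estimated correlation), and 5 and 7 at 24 h with no list call (adjusted p 0.717). Of the 12 with room to fall, 5 were higher and 1 lower at 6 h (adjusted over the list alone, 7 and 2) and 1 higher and 7 lower at 24 h (adjusted over the list alone, 3 and 8), with both calls (camera adjusted p 0.00662 and 0.0176) lost (adjusted p = 0.0755 and 0.0833 with an estimated correlation).

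The mean response at 24 h was tested against that at 6 h. Cell cycle genes were lower at 24 h: AURKB (-1.78 ± 0.16), CDC6 (-1.69 ± 0.07), HJURP (-1.61 ± 0.06), UBE2C (-1.55 ± 0.13), CDK1 (-1.51 ± 0.04) and CENPA (-1.48 ± 0.05), with ADGRG1 (-1.52 ± 0.08) and PMAIP1 (-1.49 ± 0.11). The Notch coactivator MAML3 (1.55 ± 0.10), GPR107 (1.49 ± 0.18), CXCL8 (1.49 ± 0.14), SOX10 (1.39 ± 0.11), TFPI (1.29 ± 0.18), CTNNBIP1 (1.26 ± 0.14) and LIF (1.25 ± 0.12) were higher. The other SOX10 probe set moved down in A375 (-0.91, then -1.43) and up in the other lines. Of the mitosis list 36 of 38 were lower (adjusted over the list alone, 38; camera adjusted p 8.42e-32, or 0.000552 with an estimated correlation), and of the DNA replication list 34 of 39 (adjusted over the list alone, 36; 3.60e-28, or 0.0106). MAP kinase output genes had 11 higher and 1 lower (adjusted over the list alone, 13 and 1; camera adjusted p 1.28e-06, or 0.0108 with an estimated correlation) and lineage factors had 12 higher (adjusted over the list alone, 13; 2.93e-07, or 0.0356). Calls numbered 2927, 1358 higher and 1569 lower. Without SKMEL5 A-485 6 h replicate 1 or SKMEL5 A-485 24 h replicate 1, which leaves the other lines, the count was 1706, and AURKB (-0.69) and UBE2C (-0.50) were not called. CDC6 was then -0.59, HJURP -0.34, CDK1 -0.47, CENPA -0.53, PMAIP1 -0.59 and ADGRG1 -2.27, and the medians of the mitosis and DNA replication lists were -0.39 against -0.97 and -0.99. Without either A375 A-485 array AURKB was -2.48, CDC6 -2.53, HJURP -2.44, UBE2C -2.35, CDK1 -2.23, CENPA -2.26, PMAIP1 -2.11 and LIF 0.57. With A-485 at 24 h AURKB, CDC6, HJURP and CENPA lay within 2-fold of the floor in SKMEL5, and at 6 h MAML3, TFPI and LIF did in A375. The count was 512 without scaling between arrays and 280 with the values as deposited and a floor of 1.

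In DMSO, A375 differed from the other lines in 9983 genes, 5332 higher and 4651 lower. MITF was lower in A375 (-3.73 ± 0.04, adjusted p 1.90e-10), with the melanosome protein PMEL at -6.62 ± 0.39, ST3GAL6 at -5.65 ± 0.17, IL1RAP at -5.07 ± 0.11, GAS7 at -5.07 ± 0.11 and the amino acid transporter SLC1A4 at -5.00 ± 0.13. The receptor EPHA2 (5.83 ± 0.17), DKK1 (5.65 ± 0.11), MGST1 (4.99 ± 0.09), the long noncoding RNA UCA1 (4.99 ± 0.40), WNT5A (4.23 ± 0.15), THBS1 (4.19 ± 0.04) and the AP-1 subunit FOSL1 (3.79 ± 0.08) were higher. All 15 pigmentation genes were lower (median -3.20, camera adjusted p 1.56e-07, or 0.0462 with an estimated correlation), as were 15 of 17 lineage factors (1.10e-06, or 0.0335), while 23 of 27 MITF-low genes were higher (median 2.51, camera adjusted p 1.10e-06, or 0.0142). The pigment transcripts of A375 DMSO 6 h replicate 1 enter the A375 level of this contrast, and PMEL was -7.23 without it and -6.01 without replicate 2. In A375 PMEL, ST3GAL6, IL1RAP and GAS7 lay within 2-fold of the floor at 1 or both times, as did EPHA2, MGST1, WNT5A, THBS1 and FOSL1 in 1 or both of the other lines, so these sizes are not exact.

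The scale of the arrays affected how many genes were called in each direction. Without scaling between arrays the median of all genes moved by 0.28 in SKMEL5 and 0.39 in WM2664 at 6 h, by 0.18 in WM2664 at 24 h and by 0.22 in the mean at 6 h. It moved by -0.30 and -0.11 in the differences of A375 at 6 h and 24 h, by -0.16 between the times and by 0.18 in DMSO. All changes are therefore relative to the median gene of an array. At 6 h the share of higher genes among the calls was 57.3%, 58.1% and 46.1% in SKMEL5, WM2664 and A375, against 78.3%, 87.3% and 26.8% without scaling. At 24 h it was 57.1%, 54.6% and 51.9%, against 30.5%, 68.5% and 22.9%. For the mean at 6 h it was 59.1% against 85.0%, for the differences of A375 47.0% and 50% against 19.3% and 39.2%, between the times 46.4% against 13.9%, and in DMSO 53.4% against 67.0%. Arrays centred on their median gave 70.6% and 72.6% for WM2664 at 6 h and 24 h, and 69.4% and 66.5% for the means.

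With the values as deposited and a floor of 1 the share of higher calls was 75% in WM2664 and 10.2% in A375 at 6 h, and 14.2% in SKMEL5 and 9.28% in A375 at 24 h. It was 83.3% and 44.5% for the means (55.9% at 24 h with scaling), 19.6% for the 6 h difference of A375, 11.8% between the times and 68.7% in DMSO. The median of all genes then moved by 0.38 in SKMEL5 at 6 h, by 0.50 and 0.30 in WM2664 at 6 h and 24 h, and by 0.30 in the mean at 6 h. It moved by -0.37 and -0.15 in the differences of A375, by -0.23 between the times and by 0.32 in DMSO.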

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

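The tests of RNA from another line, of array brightness and of the regroupings behind the differences and DMSO levels of A375 were chosen only after the result was seen. The rule for single arrays compared each DMSO array with the other 3 DMSO arrays of its line over the means of 25 gene lists and the brightness before scaling, and 6 of 78 such tests were passed, where chance gives about 1 in 20.

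Pigmentation genes of A375 DMSO 6 h replicate 1 had a mean log2 intensity of 7.18, far above the other DMSO arrays of A375. At 28 genes high in SKMEL5 and outside the pigment, MITF and lineage lists, the excess of this array had a median of 0.771% of the SKMEL5 level, with 25 of the 28 genes in excess, against at most 0.0841% on the other A375 arrays. At 29 genes high in WM2664 the median was 0.111%, below the 0.421% of another A375 array, which argues against RNA from WM2664. The 28 shares had quartiles of 0.477% and 1.34%. Shares of pigment genes varied: MLANA had 2.26%, PMEL 2.09%, TYRP1 1.74%, TYR 0.930%, OCA2 0.223%, TSPAN10 0.216% and SLC45A2 -0.808%. Their interquartile range was 1.70 points against at most 0.612 on the other A375 arrays. This cannot exclude 1 share of SKMEL5 RNA, since signal compression could raise shares of bright genes. A trace of SKMEL5 RNA in that sample could give the excess at the 28 other genes, and why pigment shares differ stays open. No biological explanation was tested for 1 array.

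The same measure was then taken for all 36 pairs of an array and another line, and 3 showed an excess (sign test over genes, adjusted p under 0.05, genes not being independent). WM2664 DMSO 6 h replicate 1 had 1.76% of the SKMEL5 level, with 27 of 30 genes in excess, against at most 0.0647% on the other WM2664 arrays (adjusted p 0.000303). WM2664 DMSO 24 h replicate 2 had 0.758% of the A375 level, with 30 of 37 genes in excess, against at most 0.131% (adjusted p 0.00229). The other was the A375 array above (adjusted p 0.000494). These values are consistent with traces of SKMEL5 and A375 RNA in those 2 samples, and whether cells, RNA or labelled material were mixed was not tested.

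The other arrays that stood apart by the rule for single arrays were SKMEL5 DMSO 24 h replicate 2, with mean log2 intensities of 8.07 for the senescence list, 10.1 for MYC targets of ribosome biogenesis and 5.30 for leukocyte markers; WM2664 DMSO 6 h replicate 1, with 8.66 for p53 targets; and WM2664 DMSO 24 h replicate 1, with 12.1 for housekeeping genes.

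The response to A-485 differed between A375 and the other lines in 1684 genes at 6 h and 3430 at 24 h, and between 24 h and 6 h in 2927 genes, each by a test of the difference. MITF was among them, with 0.85 ± 0.10 and -0.49 ± 0.10 for A375 at 6 h and 24 h and 0.53 ± 0.07 between the times. Single arrays decide these values: without WM2664 A-485 6 h replicate 1 the 6 h difference was 0.21 and not called, without SKMEL5 A-485 24 h replicate 1 the 24 h difference was 0.017, and without either WM2664 A-485 array the change between times was 0.24 and not called. For the mean over lines, 1 of the 27 ways to name 1 array per line as the treated one, the real one, called as many genes at each time: 5238 at 6 h against at most 2246 in another split, and 6576 at 24 h against at most 3804. With 27 splits no share below 1 in 27 can be reached. A wrong split also puts an A-485 array among those named DMSO, which widens the spread and can lower the calls by itself. These splits therefore do not exclude chance as a source of the counts. The 4 splits behind the change between times (real 2927, highest other 1882) and the 3 behind each difference of A375 (real 1684 and 3430, highest other 1250 and 2720) are too few for a share under 0.05, and the real split alone, 1 in each, was as large. For the DMSO levels of A375 the 3 splits by line (real 9983, highest other 9443) are too few as well, and the real one alone was as large.

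Probe sets of very bright genes showed smaller changes than the next probe set of the same gene. Over 16 genes whose brightest probe set lay above a log2 intensity of 12, its change was smaller in 15, with a median difference of sizes of -0.25 (sign test p 5.19e-04), and in 3 bins of lower brightness the median was -0.01, -0.07 and -0.18 from the dimmest to the brightest. In the last of these the brightest set also changed less for 8 of 9 rises, while the top bin held 1 rise. The values are consistent with signal compression, so falls of the brightest genes may be understated. Different transcripts read by the probe sets were not tested and stay open.

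The A-485 arrays were brighter than the DMSO arrays before scaling at 6 h, by a mean of 0.316 (log2). In 2 of the 27 splits the difference was as large, the highest other being 0.340, so array to array variation in brightness cannot be excluded and may account for it. At 24 h the difference was 0.120, as large in 11 of 27 splits. A shift of total RNA with A-485 was not tested and stays open, since the scaling removes it.

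Data outside the comparisons also held signal. Of 5636 bright enough probe sets without 1 gene symbol, 38 differed at least 2-fold in the mean over lines at 6 h, 6 higher and 32 lower, and 63 at 24 h, 19 higher and 44 lower.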

How the results depend on the processing

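Scaling to the 75th percentile, only genes above the floor on all arrays, leaving out the 3 DMSO arrays with transcripts of another line, and lists of genes with room to fall were chosen after seeing the data. Of 4686 values of called genes under the alternatives, 4328 kept direction and call, 350 lost the call and 8 reversed. Of 2220 list medians there, called or not, 2106 kept their status, 70 lost the call, 44 gained one and 0 called ones reversed. With an array left out 4912 of 5026 gene values kept both, 110 lost the call and 4 reversed. The cause was not tested, except that a fold threshold lowers a count by construction. Signal over background limits the dim genes: a group at the floor has no level of its own.

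Without scaling between arrays the calls were 834 in SKMEL5 at 6 h, 425 in A375 at 6 h, 1228, 1339 and 632 in SKMEL5, WM2664 and A375 at 24 h, 2915 for the mean at 24 h, 398 and 801 for the differences of A375 at 6 h and 24 h, and 512 for 24 h minus 6 h, and MITF in SKMEL5 at 24 h was -0.64 and not called. The setting planned first, values as deposited with a floor of 1, gave 114, 511 and 177 in SKMEL5, WM2664 and A375 at 6 h, 657, 503 and 237 at 24 h, 2741 and 1662 for the means, 51 and 201 for the differences and 280 between the times, and MITF was -1.08 and -1.10 in SKMEL5 and A375 at 6 h and -0.64 in SKMEL5 at 24 h, none of these 3 called. In both settings GPR143 and MYO5A in the mean at 6 h turned to 0.031 and 0.026, and MLPH in the 6 h difference of A375 to -0.10. The floor of 1 alone gave 1037 and 1472 in A375, 645 and 1941 for the differences and 1855 between the times, and the floor of 16 gave 991 for the 6 h difference. Genes above the floor on all arrays gave 1175 in A375 at 6 h and 798 and 2222 for the differences. With the mean of a gene's probe sets MITF in the 24 h difference of A375 was 0.047, which includes a set at the floor in A375, and without cross-hybridizing probe sets SETD4 in SKMEL5 at 6 h was -0.016.

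At least 2-fold differences numbered 511, 720 and 384 in SKMEL5, WM2664 and A375 at 6 h, 1104, 914 and 512 at 24 h, 305 and 402 for the means, 451 and 1013 for the differences, 179 between the times and 3374 for DMSO, with MITF in SKMEL5 at 24 h (-0.50) below it. An additive fit gave 2777 and 2264 for the means. SKMEL5 against the other lines gave 984 at 6 h and WM2664 against them 2193 at 24 h. List calls numbered 105, 55 with an estimated correlation and 209 with fry. The 2-fold threshold does not apply to lists, and list totals were not computed for fits to 1 time or without an A-485 array.

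With the replicate number as a block within each time 24 h minus 6 h had 1582 calls, and with a block common to all groups 2652; no other count moved by over 1.5 times under a block. The numbers share no common deviation: the correlations of the deviations of same-numbered pairs ran from -0.0357 to 0.0596 with a median of 0.00962, and 0 of 15 were above 0.1.

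Without the 3 DMSO arrays that carried transcripts of another line A375 at 6 h had 1163 calls and no other count moved by over 1.5 times. The calls of PIK3IP1 (1.91) in SKMEL5 and LMO2 (1.87) and MXD1 (1.39) in A375 ended at 6 h, as did those of EP300 (0.59 and 0.60), SYT7 (1.86) and UNC119 (1.78) at 24 h and, in the differences of A375, DDIT4 (-1.83) at 6 h and CHAC1 (3.73) at 24 h.

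With each array left out in turn, calls ran from 2413 to 3300, 2877 to 3731 and 1485 to 1896 in SKMEL5, WM2664 and A375 at 6 h, 4406 to 4981, 3894 to 4682 and 2049 to 2565 at 24 h, 3733 to 5438 and 4950 to 6752 for the means, 1364 to 1897 and 2826 to 3747 for the differences of A375, 1706 to 3291 between the times (lowest without SKMEL5 A-485 6 h or 24 h replicate 1), 9509 to 10091 for DMSO and 104 to 108 for lists. A lone array left in a group was assumed to vary like the other groups. A line's A-485 array was never left out of its own comparisons, so their ranges and kept calls, MITF included, cannot test it. Some values turned. In the differences of A375, MLPH at 6 h ran from -0.18 (without WM2664 A-485 6 h replicate 1) to 0.84 and MITF at 24 h from -0.99 to 0.017 (without SKMEL5 A-485 24 h replicate 1). In the mean at 24 h, MC1R ran from -0.83 to 0.0071 and RAB38 from -0.96 to 0.052 (highest without WM2664 A-485 24 h replicate 1), and the median of the MITF-low list from -0.59 to 0 (without A375 A-485 24 h replicate 1).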

Other observations

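The test of genes high in 1 line was written before its result was seen, and the values of single genes and lists here were planned. Immediate early genes, which respond first to signals, went both ways. Of 22 measured in SKMEL5 at 6 h, 11 rose and 4 fell (adjusted over the list alone, 12 rose and 5 fell). In WM2664 8 rose and 4 fell (adjusted over the list alone, 9 rose and 4 fell), and in A375 4 rose and 7 fell (adjusted over the list alone, 6 rose and 8 fell). EGR1 and CCN2 were among the higher and KLF6 lower in each line (-1.46, -1.78 and -2.16). At 24 h the counts were 11 higher and 4 lower, 8 and 5, and 5 and 4. The list was called in none of the 6 comparisons (camera adjusted p 0.198, 0.481 and 0.88 at 6 h and 0.128, 0.198 and 0.94 at 24 h). Of 21 genes of the endoplasmic reticulum and integrated stress response, 4 rose in SKMEL5, 2 rose and 2 fell in WM2664 and 2 rose and 3 fell in A375 at 6 h. At 24 h 2 rose and 14 fell (adjusted over the list alone, 2 rose and 15 fell) in SKMEL5. In WM2664 8 fell, and as many adjusted over the list alone, and in A375 1 rose and 2 fell, and as many adjusted over the list alone. The serine synthesis enzyme PSAT1 was at -1.97 and -1.33 and the cystathionine enzyme CTH at -1.26 and -1.44 in SKMEL5 and WM2664. Those list calls (camera adjusted p 0.000363 and 0.00172) were lost (adjusted p = 0.512 and 0.466 with an estimated correlation). Among 24 p53 targets CDKN1A rose in SKMEL5 and WM2664 at both times (1.3, 1.5, 1.39 and 1.53), while the list had 4 higher and 4 lower in WM2664 and 1 and 5 in A375 at 6 h, 3 higher in SKMEL5, and 4 and 6, 5 and 5, and 2 and 2 at 24 h, with no list call.

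In the BCL2 family of 15 genes, the survival factor MCL1 rose in the 3 lines at 6 h (1.09, 1.21 and 0.35), the survival gene BCL2A1 fell in SKMEL5 and WM2664 (-0.76 and -1.23), and the death-promoting BIK rose in SKMEL5 from near the floor (0.95) and fell in A375 (-2.08). The family had 3 higher and 3 lower, 2 and 2, and 1 and 2 at 6 h, and 5 and 6, 3 and 5, and 2 and 2 at 24 h. Of 26 genes of the acetylation machinery, 6 rose and 5 fell, 8 and 5, and 4 and 3 at 6 h, and 12 and 3, 9 and 4, and 3 and 3 at 24 h, with CITED1, which binds p300 and CBP, at the floor in SKMEL5 and WM2664 at 24 h (at least as far as -2.92 and -3.86) and CITED2 at -1.95 in A375. Of 29 interferon genes, 2 rose and 1 fell, 3 and 2, and 1 and 2 at 6 h, and 8 rose in SKMEL5, 4 rose and 3 fell in WM2664 and 4 and 4 in A375 at 24 h, with IFIT1 higher in each line at 6 h, from near the floor in SKMEL5 and A375 (1.22, 0.53 and 0.92). Of 17 NF-kappaB targets 4 fell in SKMEL5, 2 rose and 3 fell in WM2664 and 5 fell in A375 at 6 h (camera adjusted p 0.00237 in A375, lost at adjusted p = 0.0755 with an estimated correlation, but held at 0.0255 over the 12 members with room to fall), and 1 and 2, 2 and 2, and 3 and 2 rose and fell at 24 h. The 26 hypoxia genes had 3 higher and 6 lower, 2 and 7, and 3 and 5 at 6 h, and 7 and 8, 12 and 6, and 5 and 6 at 24 h. The 17 cholesterol genes had 2 and 1, 2 and 2, and 3 higher at 6 h, and 2 and 2, 1 and 6, and 2 and 1 at 24 h, with the sterol reductase TM7SF2 higher in each line at 24 h from DMSO levels at the floor in SKMEL5 and WM2664 (by at least 1.83 and 1.38) and close to it in A375 (0.60) and the WM2664 call at 24 h (camera adjusted p 0.033) lost (adjusted p = 0.135 with an estimated correlation).

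The 29 lysosome genes had 6 lower in SKMEL5, 2 higher and 6 lower in WM2664 and 2 and 1 in A375 at 6 h, and 2 and 7, 4 and 9, and 5 and 1 at 24 h. Of 11 heat shock genes 5 rose in SKMEL5, 4 rose and 1 fell in WM2664, HSPA4L among the higher (1.26), and 2 and 2 in A375 at 6 h, and 4 fell, 3 rose and 4 fell, and 1 rose and 3 fell at 24 h. The WM2664 call at 6 h (camera adjusted p 0.0123) was lost (adjusted p = 0.24 with an estimated correlation). Markers of other cells were few. Of 8 fibroblast markers 2 fell in WM2664 and 1 in A375 at 6 h, and 1 rose and 2 fell in WM2664 and 1 fell in A375 at 24 h, with POSTN at -1.22 in WM2664. Of 7 keratinocyte and epithelial markers, 1 rose and 1 fell in SKMEL5 at each time, 2 fell in A375 at each time, with KRT14 at -0.89 and -1.76, and 1 rose in WM2664 at 24 h, and the A375 call at 24 h (camera adjusted p 0.0281) was lost (adjusted p = 0.184 with an estimated correlation). In limma 0 of 3 leukocyte markers were called in the 6 comparisons, and 1 was lower in A375 at 6 h at an unadjusted p under 0.05. Of 11 housekeeping genes limma called 0 at 6 h, where 1 was higher in WM2664 at an unadjusted p under 0.05, and at 24 h 1 rose and 2 fell in SKMEL5, TUBB among the lower (-1.29), and 2 rose in WM2664.

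A hypothesis was that transcripts high in 1 line rely more on p300/CBP catalysis than others. Genes at least 4-fold higher in a line than in both others were picked from DMSO arrays of the other time. Their median response was set against 10000 random lists matched on size and level. In 6 of 6 line-time pairs it lay below the 5th percentile of random lists, and below all. At 6 h it was -0.55 over 230 genes in SKMEL5, -0.54 over 216 in WM2664 and -0.43 over 337 in A375, with 108, 128 and 150 lower, and at 24 h it was -0.44 over 212, -0.57 over 220 and -0.57 over 309, with 99, 134 and 165 lower. Whether MITF-low or MITF program genes fell more than these was not tested. The values fit the hypothesis in these lines but do not tell p300/CBP from an untested general loss of unstable or highly transcribed messages.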
